A study of Homo sapiens with 3 samples.

How the data were processed

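Low-pass whole-genome sequencing of genomic DNA was used to estimate chromosome copy number in 3 libraries of human embryonic germ cell-like cells (hEGCLCs). These are pluripotent cells reprogrammed in culture from human primordial germ cell-like cells. All 3 libraries carry the labels hEGCLC and P5 and come from BTAG, a human induced pluripotent stem cell line with fluorescent reporters for the germ cell genes PRDM1 (BLIMP1) and TFAP2C. The libraries are numbered C1, C2 and C5 in the labels and are called lines here. The labels do not say whether they came from separate derivations. There is 1 library per line, a single group and no control library.

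The deposited files hold 1 linear ratio per bin of 1 Mb, which the authors scaled so that a typical bin lies near 1. Per the submitters' processing notes, cutadapt 4.7 and Bowtie2 2.5.1 were used and the genome build was GRCh38. The tool that counted reads per bin, the correction for GC content or mappability and the rule that left bins empty are not given in the sources used here. Each file lists 3113 bins. Of the 2897 autosomal bins, 1941 (67.0%) hold a value, and the same bins are filled in all 3 lines. The values are ratios and not counts, so the sequencing depth is unknown and no counting interval is given. Chromosomes X and Y were left out of every result.

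The bin grid is not that of GRCh38. In the RefSeq gene table of GRCh38.p14, 293 genes on 7 autosomes lie past the last bin of their chromosome. Of the 8 usable bins that lie mostly past the last GRCh38 gene of a chromosome or inside its longest gene-free stretch, 1 had a ratio under 0.3 and 7 lay in all 3 lines at a fixed log2 distance below the surrounding bins, which is described in the closing section. Of the other 1933 bins, 0 had a ratio under 0.3 and 11 lay at that distance below. This definition of a low bin was chosen after the values were seen. Reads were treated as placed on GRCh38, as the processing notes name, and genes were assigned to bins by their GRCh38 position. Bin coordinates are those of the files. Gene coordinates are not given.

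Ratios were divided by the autosomal median of each library, which was 1.00 in C1, 0.991 in C2 and 0.991 in C5 as deposited. Bins with a ratio averaged over the lines under 0.3 or over 2.2 were left out, which removed 1 bin and left 1940. The copy number of an autosome or arm was 2 times the median ratio of its bins. Arms were separated at the longest gene-free stretch of each chromosome in the GRCh38 gene table, and the short arms of the acrocentric chromosomes were left out, which gave 39 arms. The GC correction foreseen in the design could not be made without a genome sequence.

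No significance test was possible between groups, since the series has a single group. A two-sided sign-flip permutation test over 3 lines cannot go below p = 0.25. Gains and losses were called by a rule of size fixed before the data were examined: 2.3 copies or more, or 1.7 copies or less, the value of a single-copy change in 30% of cells. Segments were found by recursive splitting of the log2 ratios, with 1999 permutations, a permutation p under 0.001 for each split and at least 5 bins per segment. This was done against 2 copies and against the mean of the other 2 lines. The copies of a segment were taken from the mean of its log2 ratios, not from a median. The local copy number at a gene was taken from the bin of its midpoint and 2 usable bins on each side. Where that bin held no value (PRDM14, GRB2, POU5F1, KLF4 and KIT), only the 4 neighbouring bins were used, and fewer bins were used at the end of a chromosome. Between lines, the ratio of a line to the mean of the other 2 was taken per bin, its median over each autosome was expressed in copies, and this was set against 10000 random runs of as many consecutive bins from the other autosomes, as a description of these libraries.

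The text names all chromosomes and arms past the rule, the 3 highest and 3 lowest autosomes, the 3 largest differences between lines, a fixed set of autosomes and arms (1, 8, 10, 12, 17, 18, 20, 22, 1q, 10p, 12p, 12q, 17p, 17q, 18q, 20q), the stretch from ID1 to DNMT3B at 20q11.21, and from 4 fixed gene lists any gene past the rule, the highest and the lowest member, and, of the list of genes gained in culture or germ cell tumours, those on 12p and 20q. Some genes of these lists are not reported here and are left out of the counts. The design covered bin filters, centring, mean or median, the size of a call, segment length, window size and leaving out each line. Using the ratios as deposited, leaving out bins with signs of outlier treatment, moving the gene window and comparing mean ratios or autosome medians between lines were added after seeing the data.

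The calling rule was applied to simulated data made from these libraries, by raising or lowering each autosome of each line in turn (66 chromosome and line pairs). The measured ratios were only multiplied and no counting noise was added. The rates for whole autosomes therefore follow largely from the size of the rule and the measured medians. A single-copy gain in 50% of cells was called in 100% of pairs, in 40% of cells in 98.5%, in 30% of cells in 34.8% and in 20% of cells in 0%. Losses were called in 100% of pairs at 35% of cells and in 45.5% at 30%. Single-copy gains in all cells placed at random were called in 89.4% of 66 insertions of 5 bins, in 100% of 66 insertions of 10 bins and in 0% of 66 insertions of 1 bin. The last value followed largely from the settings, since a segment needed at least 5 bins and a mean of 2.3 copies. In 50% of cells, gains of 5 bins were called in 60.6% and gains of 10 bins in 92.4%. In 30% of cells, gains of 5 bins were called in 12.1%, of 10 bins in 43.9% and of 20 bins in 46.7% of insertions. These gains were inserted after any outlier treatment made before deposit, so the rates do not cover its effect on a real gain. No loss of a segment was inserted. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.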

Results

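Genomic DNA of 3 hEGCLC lines, labelled C1, C2 and C5 and taken at P5, was profiled by low-pass sequencing to read the copy number of each chromosome after reprogramming from primordial germ cell-like cells. The 3 lines form the only group, and each is a single library. Values are copies relative to a median autosomal bin set at 2 in each library. A change of ploidy that affects all autosomes alike can therefore not be read from them. Over the 1940 bins used, the SD between bins was 0.132 copies in C1, 0.134 in C2 and 0.136 in C5.

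All 22 autosomes lay near 2 copies in all 3 lines, and none was called gained or lost. The 66 values of an autosome in a line ranged from 1.90 copies (chromosome 21 in C5) to 2.04 copies (chromosome 5 in C2). The highest means were those of chromosome 3 at 2.02 ± 0.0032 copies, chromosome 5 at 2.02 ± 0.013 and chromosome 12 at 2.02 ± 0.010 (SD, n = 3 for this and all following means). The SD covers differences between the libraries and leaves out effects of bins that all of them share. It does not gauge the distance of a mean from 2 copies. The lowest were those of chromosome 21 at 1.93 ± 0.027, chromosome 17 at 1.96 ± 0.0036 and chromosome 16 at 1.96 ± 0.0068. The largest departure of a mean from 2 copies, that of chromosome 21, equals the value of a single-copy loss in 6.97% of cells. Chromosome 21 rested on 21 bins and chromosome 3 on 148.

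The autosomes in which human pluripotent stem cells most often acquire changes in culture were also near 2 copies. Chromosome 1 had 2.01 ± 0.00044 copies, chromosome 8 had 1.98 ± 0.0059 and chromosome 20 had 1.97 ± 0.011. Chromosome 12, gained as a whole or by its short arm in culture, and chromosome 17 are given above. Chromosome 10 had 1.97 ± 0.0052 copies, chromosome 18 had 1.98 ± 0.023 and chromosome 22 had 1.98 ± 0.035. In the simulation on these libraries, a gain of a whole autosome in 50% of the cells of a line was called in all pairs. One in 20% of cells was called in none. Both outcomes followed largely from the size of the rule, since the measured ratios were only multiplied.

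**Figure D1:**
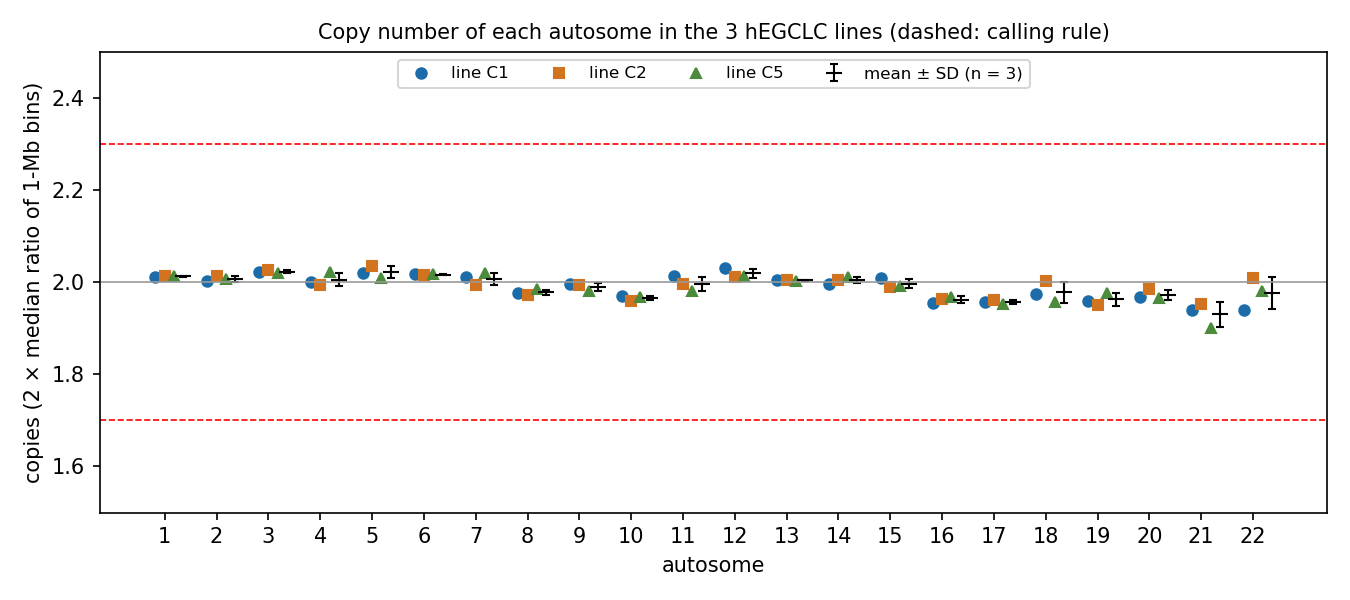
Copies of each autosome (vertical axis, 2 times the median ratio of its bins of 1 Mb) in lines C1, C2 and C5 (coloured symbols), with the mean and SD of the 3 lines (black) and dashed lines at 1.7 and 2.3 copies. All 66 values lie between 1.90 and 2.04 copies, inside the dashed lines.

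No chromosome arm was past the rule in any line. The 117 values of an arm in a line ranged from 1.88 copies (16p in C5) to 2.05 copies (5q in C2). The short arm of chromosome 12, whose gain as an isochromosome is the hallmark of testicular germ cell tumours, had 2.00 ± 0.029 copies over 27 bins, and 12q had 2.02 ± 0.00033. The long arm of chromosome 1 had 2.00 ± 0.0080 copies and that of chromosome 17 had 1.98 ± 0.0099, while 17p had 1.93 ± 0.022. The long arm of chromosome 20 had 1.98 ± 0.0032 copies. Of the arms that are recurrently lost in culture, 10p had 1.94 ± 0.0090 copies and 18q had 1.98 ± 0.024.

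Splitting the chromosomes into segments gave a single segment past the rule, a loss called in C2 alone. It covered 6 usable bins between positions 1000001 and 9000000 of chromosome 8 (bin coordinates of the files) and stood at 1.68 copies in C2. Over the same bins C1 had 1.72 and C5 had 1.74 copies, both short of the rule, so the stretch was low in all 3 lines. Bin ratios fell towards the ends of the bin grid in all lines (closing section). Whether that accounts for this stretch was not tested. Set against the other 2 lines, chromosome 8 in C2 was not split and stood at 2.00 copies. Against the mean of the other 2 lines no segment was past the rule in any line, and segments ranged from 1.96 to 2.02 copies. In the simulation, single-copy gains of 5 bins were called in 89.4% of insertions when present in all cells and in 12.1% when present in 30% of cells. Losses of segments were not simulated, so these rates do not apply to the call in C2. The only other split chromosome was chromosome 6 in C1, where 39 bins between positions 93000001 and 144000000 stood at 2.09 copies, against 2.06 in C2 and 2.07 in C5. The loss on chromosome 8 was not called with segments of 3 bins allowed or with all bins kept, which returned 1 bin at the other end of chromosome 8. With at least 10 bins per segment, a stretch of 6 bins could not be called. The loss was still called in C2 with a stricter bin filter (1.67 copies) and with ratios as deposited (1.66 copies). It was also called without bins showing outlier treatment or lying past chromosome ends or in gene-free stretches (1.67 copies).

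The band 20q11.21, gained recurrently in human pluripotent stem cells, showed no gain past the rule in any line. Its stretch from ID1 to DNMT3B covered 2 bins, from 31000001 to 33000000 of chromosome 20, and had 1.91 ± 0.017 copies. The stretch was placed by GRCh38 gene positions on a bin grid that is not that of GRCh38. No gain of 2 bins was simulated, and a gain of 2 bins need not move the median of a window of 5. A smaller gain, or one in few cells, is not excluded. The windows at ID1, a transcriptional regulator of differentiation, at BCL2L1, the anti-apoptotic gene taken as the driver of the gain, and at TPX2, a spindle assembly factor, were the same 5 bins, from 24000001 to 34000000 on both sides of the centromere, and gave 1.89 ± 0.028 copies. The window at DNMT3B, a de novo DNA methyltransferase, gave 1.98 ± 0.027. With the windows moved by up to 3 bins, the means at these 4 genes ranged from 1.78 to 2.07 copies, so their side of 2 copies depended on the placement. On 12p, the windows at the pluripotency genes NANOG, GDF3 and DPPA3 were shared and gave 1.98 ± 0.028 copies, and CCND2 (cyclin D2) gave 1.98 ± 0.048. The single bin that holds NANOG, GDF3 and DPPA3 gave 2.25 ± 0.11 copies, with 2.34 in C1, past the rule in that line alone.

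Of the 12 reported genes gained in culture or in germ cell tumours, 0 were past the rule in windows of up to 5 bins, with a median of 1.98 copies. In a window of 1 bin, NANOG, GDF3 and DPPA3 were past it in C1. The lowest were ID1, BCL2L1 and TPX2, as above, and the highest was MDM4 on 1q, an oncogene gained in several tumours, at 2.12 ± 0.056 copies. Of the 4 reported genes lost in culture or tumours, 3 were measured and 0 were past the rule. The lowest was GATA3 on 10p at 1.90 ± 0.031 copies and the highest was CDKN2A, a cell cycle inhibitor on 9p, at 2.00 ± 0.028. SALL3 on chromosome 18 lay past the end of the bin grid and has no value.

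Among 9 core and naive pluripotency genes, 1 was past the rule. DNMT3L, a cofactor of DNA methylation on chromosome 21, stood at 1.6999 copies in C1 and 1.68 in C5, both called, and at 1.73 in C2, with a mean of 1.7004 ± 0.025. Its window held only 3 bins, from 42000001 to 45000000, the last usable ones of the chromosome. PRDM14, a regulator of germ cell specification and pluripotency on chromosome 8, was the highest at 2.13 ± 0.022 copies, from 4 neighbouring bins, since its own bin held no value. Of the 8 germ cell genes, 0 were past the rule. The lowest was SOX17, which specifies human germ cells, at 1.96 ± 0.035 copies and the highest was DND1, an RNA-binding protein of germ cells, at 2.04 ± 0.072. The call at DNMT3L ended when bins with signs of outlier treatment were left out (mean 1.81 copies) and in a window of 11 bins (mean 1.82 copies).

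**Figure D2:**
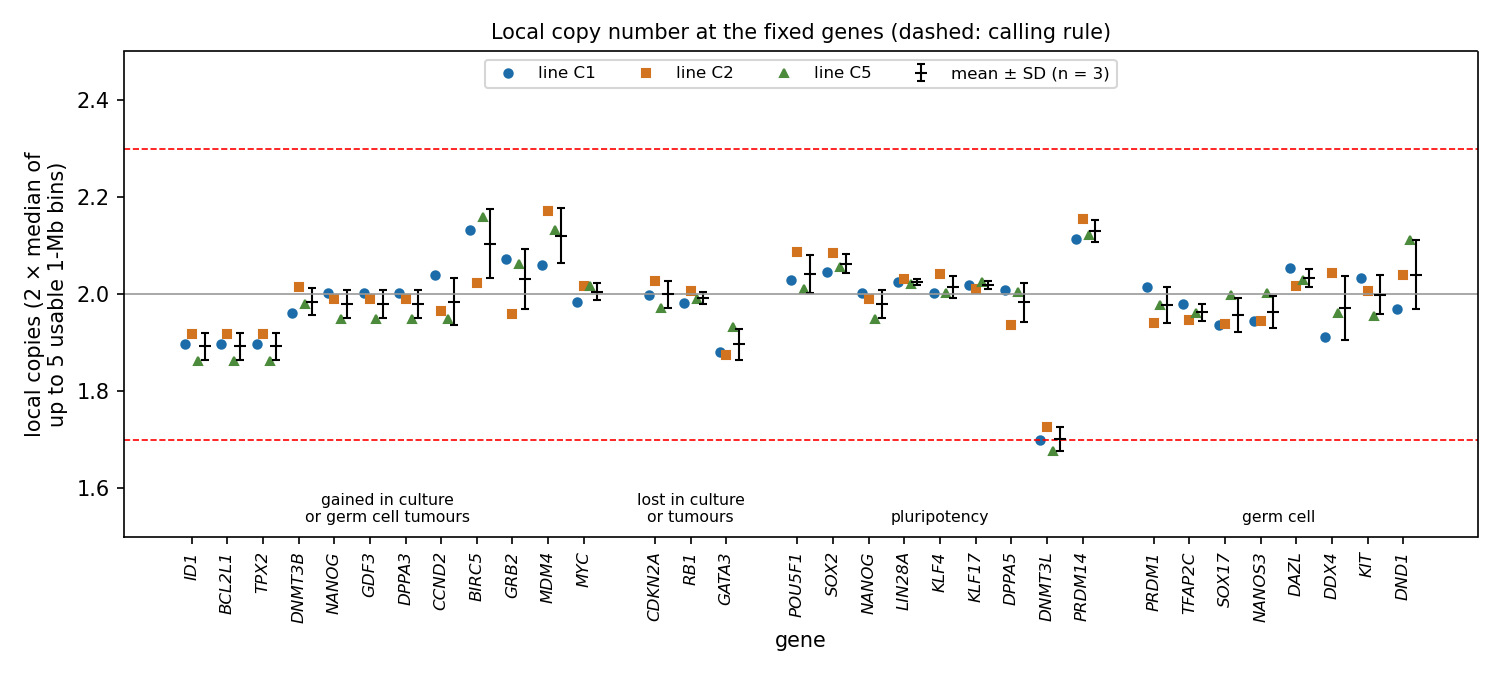
Local copies (vertical axis, 2 times the median ratio of up to 5 usable bins of 1 Mb) at the genes of the 4 fixed lists in lines C1, C2 and C5 (coloured symbols), with the mean and SD of the 3 lines (black) and dashed lines at 1.7 and 2.3 copies. DNMT3L, at 1.7004 ± 0.025 copies, is the only gene that reaches a dashed line.

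No autosome of a line differed from the other 2 lines by 0.3 copies or more. Taken bin by bin, as the median over an autosome of the ratio of a line to the mean of the other 2, the largest differences were on chromosome 22 in C1, lower by 0.041 copies (-0.041 as measured), on chromosome 22 in C5, higher by 0.031 copies, and on chromosome 11 in C5, at -0.026 copies. The largest of these equals a single-copy difference in 4.07% of cells. Taken instead as the difference between the autosome medians given above, the largest were -0.056 copies on chromosome 22 in C1 (5.59% of cells), 0.049 on chromosome 22 in C2 and -0.046 on chromosome 21 in C5, where the bin-wise difference was 0.010. Of the 66 bin-wise values, 6 lay outside the central 95% of random runs of bins, where 3.3 would lie outside by the definition of the interval. They were chromosome 22 in C1, chromosome 11 in C5, chromosome 9 in C2 at 0.023 and in C5 at -0.024 copies, and in C1 chromosome 5 at -0.015 and chromosome 12 at 0.015 copies. By size alone, chromosomes 5 and 12 in C1 exceeded 94.99% and 92.41% of random runs. The 66 values are not independent, since each line enters the comparisons of the others. The count of 6 against 3.3 therefore does not establish an excess. Across bins, which are not independent replicates, the lines correlated with Pearson's r of 0.754 for C1 and C2, 0.738 for C1 and C5 and 0.740 for C2 and C5.

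**Figure D3:**
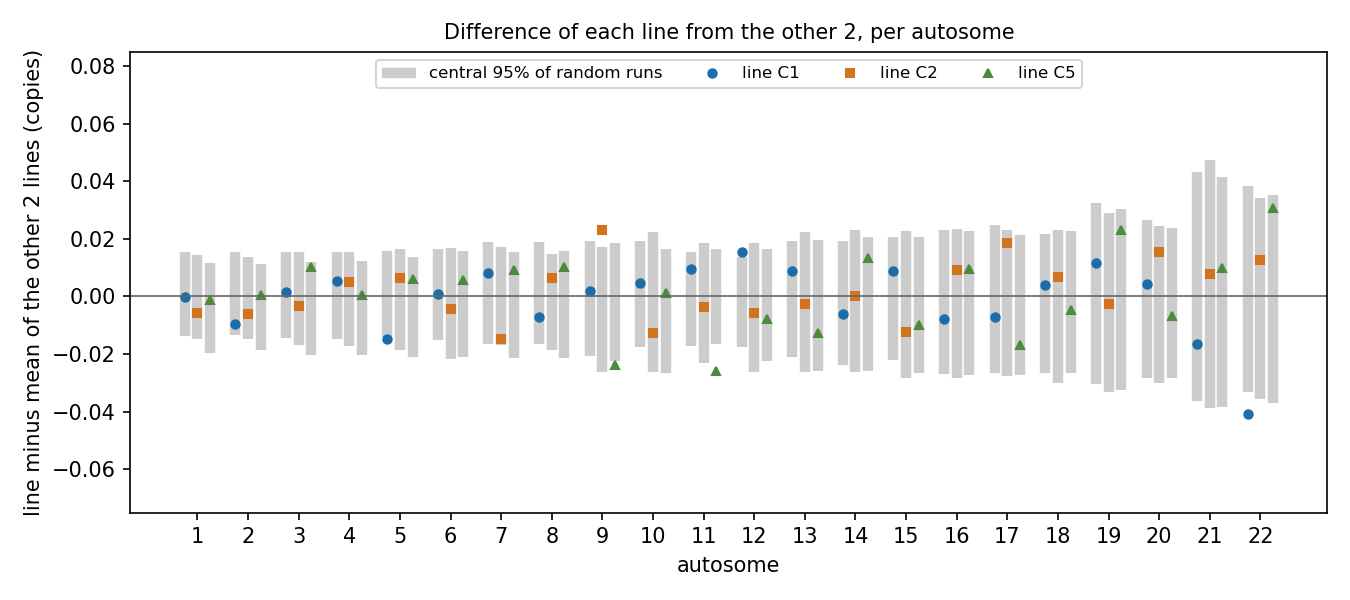
Bin-wise difference of each line from the mean of the other 2 lines in copies (vertical axis, median over bins) for each autosome, with grey bars for the central 95% of 10000 random runs of as many bins from the other autosomes. The points lie within 0.041 copies of 0, and 60 of 66 lie inside the grey bars.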

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

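The settings without bins showing outlier treatment, with the window moved, with ratios as deposited, without end bins and with mean ratios or autosome medians between lines were chosen after seeing the data. No whole autosome, arm, segment against the other lines or difference between lines was called in any run. This held with a rule of 0.2 copies (also 0.1 between lines). A rule of 0.5 copies, or a line left out for autosomes and arms, could add no call. The means of autosomes moved by at most 0.026 copies, with the mean over bins in place of the median on chromosome 7. The means of arms moved by at most 0.041, on 7q under the same setting. Means at genes moved more, by at most 0.269 copies, at NANOG in a window of 1 bin. With the window moved by 3 bins, DNMT3B went from 1.98 to 1.78 copies towards the chromosome start, and ID1, BCL2L1 and TPX2 went from 1.89 to 2.07 towards its end. The segment count against 2 copies (1, on chromosome 8 in C2) became 0 without a bin filter, 0 with a rule of 0.5 copies and 0 with segments of 3 bins allowed. It became 2 with at least 10 bins, where the 6 on chromosome 8 could not be called. A stretch on chromosome 2 was then called in C2 and C5 at 1.676 and 1.697 copies. C1 had 1.74 over the same bins, short of the rule. The stretch ran from 86000001 to 114000000, where only 11 bins were usable, and was low in all 3 lines. Leaving out each line in turn gave 1 segment, or 0 without C2, the only line with the call. The gene count (1, DNMT3L) became 0 with a rule of 0.5 copies, 0 in a window of 11 bins, 0 without bins showing outlier treatment, alone or together with bins past chromosome ends or in gene-free stretches (1 when only the latter were left out), 0 with the window moved by 3 bins towards the chromosome start, and 4 in a window of 1 bin, which added NANOG, GDF3 and DPPA3 at 2.25 ± 0.11 copies (2.34 in C1, past the rule in that line alone). Except where a value above shows it, the cause was not tested. No paired analysis was possible because the series has a single group. The planned loess span, the fit without GC correction, the GC term between lines and the ratio of summed counts were not run, since no genome sequence or counts were used here. Depth is unknown, and the simulation, made without counting noise, gives the reach of the rule rather than a measured detection limit. In it, gains of a whole autosome in 25% of cells were called in 0% of pairs. Single-copy gains of 1 bin were called in 0% of insertions, which followed largely from the minimum of 5 bins per segment. Gains of 5 bins in 30% of cells were called in 12.1%.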

Other observations

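All tests in this part were chosen after the result was seen, except the gene density test, the test without bins near the ends and the test on gene-poor bins for autosomes 16 to 22.

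Outside whole chromosomes and listed genes, local copy number was read in windows. Of 1852 windows of 5 consecutive usable bins, 9 were past the rule in any line, 7 of them low and 2 high, and 0 were past it in all 3 lines. Neighbouring windows overlapped, so the 9 need not be separate sites. There were 6 such windows in C1, 5 in C2 and 0 in C5, and all windows ranged from 1.66 to 2.41 copies in C1, from 1.697 to 2.33 in C2 and from 1.73 to 2.295 in C5. In those windows a line past the rule differed from the mean of the other 2 by at most 0.135 copies. Bin ratios, expressed as copies, fell towards the ends of the bin grid in all 3 lines. Whether copy number itself fell there was not tested. Bins within 5 Mb of an end of the grid had a median of 1.92 ± 0.011 copies (SD, n = 3 lines), those from 5 to 10 Mb had 1.96 ± 0.0093, those from 10 to 20 Mb had 1.98 ± 0.0086 and those over 20 Mb had 2.01 ± 0.00079.

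Single bins showed the largest differences between lines. On chromosome 2 a bin had 1.72 copies in C1 against 1.16 in C2 and 1.19 in C5, and on chromosome 17 a bin had 2.79 in C1 and 2.75 in C2 against 2.19 in C5. On chromosome 4 a bin had 1.74 in C1 and C2 against 1.38 in C5, and on chromosome 8 a bin had 2.26 in C1 against 2.70 in C2 and 2.75 in C5. In each library, however, 21 to 23 bins lay at exactly the same log2 distance from the median of the 21 usable bins around them (0.17 in C1, 0.17 in C2 and 0.18 in C5, to within 1e-06), while no other distance was shared by more than 3 bins. In 4 of the 4 bins above, the line or lines nearer to the surrounding bins were those at this fixed distance. A candidate explanation of the differences is outlier shrinkage before deposit, with outlying bins drawn towards their neighbours. A copy number change in one line stays open, since the line that differed held a value not at the fixed distance in only 1 of the 4 bins and the other values appear to have been replaced.

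Bins at chromosome ends and in long gene-free stretches were low in all 3 lines. The bin from 145000001 to 146000000 of chromosome 8 had ratios of 0.080, 0.083 and 0.085 as deposited in C1, C2 and C5, whereas the last bin, from 146000001 to 146364022, had 0.824, 0.829 and 0.822. Of the 8 usable bins lying mostly past the last GRCh38 gene or in the longest gene-free stretch, 100% were low by a definition chosen after the values were seen, against 0.569% of other bins. Only 1 of the 8 had a ratio under 0.3, and the other 7 lay at the fixed distance below their neighbours, so that their own values may have been replaced. The pattern is consistent with reads placed on GRCh38 counted on bins of another assembly only if those 7 bins held less before such a replacement, which the files do not show. No biological explanation was tested, as the design has a single group.

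Autosomes 16 to 22 all had a mean under 2 copies (7 of 7), as did 5 of the 15 larger autosomes. The bins of autosomes 16 to 22 had a median 0.042 ± 0.0052 copies lower than those of autosomes 1 to 15 (SD, n = 3 lines). This grouping was not part of the design and was made from the observed means, so these values only describe it. Chromosome 10, at 1.965 copies, lay below chromosomes 18 (1.978), 20 (1.972) and 22 (1.976). The tables argue against gene density as the whole cause: bins of autosomes 1 to 15 matched on gene density showed only 7.91% of the deficit. Leaving out bins within 10 Mb of the ends removed -7.34% of the deficit on average (-21.5% in C1, 7.19% in C2 and -7.69% in C5). By the criterion fixed before this test, that result counts against proximity to chromosome ends as the cause. The test does not reach the decline beyond 10 Mb. In a comparison added afterwards, bins of autosomes 1 to 15 matched on distance to the end showed 61.1 ± 6.38% of the deficit. Proximity to chromosome ends therefore stays open. A loss of these chromosomes in a small share of cells cannot be told apart from it: gene-poor bins of autosomes 16 to 22 showed 97.0% of the deficit on average, ranging from 58.3% in C2 to 122% in C5, and GC content was not used here.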
